A study of Homo sapiens with 39 samples.

How the data were processed

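PolyA RNA was sequenced from THP-1-derived macrophages on 13 materials, 3 libraries each, with a stranded TruSeq mRNA kit, per the labels' protocols. Cells were differentiated with phorbol ester, rested and seeded on materials coated with fibronectin, per the labels. The deposited file holds whole-number read counts per gene, not normalised, for 58929 gene IDs in 39 libraries, and 33021 of these had at least 1 count. The tools named in the submitters' processing notes are bcl2fastq, FastQC 0.11.5, STAR 2.5.3a, featureCounts 1.6.0 and R 4.4.0, with GRCh38. Those notes assign no roles, and the annotation release and the strand setting of the counting are not given in the sources used here. Because the strand setting is not stated, antisense and overlapping genes are uncertain. Pseudogenes and near-identical copies were treated as uncertain too.

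Libraries were grouped by the material variant in the labels. Gene IDs are those of the count table, names came from a symbol table that matched 58517 IDs, and coordinates came from GENCODE 29 (GRCh38) by stable ID, which matched 58656 IDs. Names were found for 58921 IDs in all. Totals ran from 14782148 to 23815163 counts per library. No pair of libraries of one material agreed within counting noise, since chi-square per degree of freedom ran from 1.36 to 9.09, so none were merged, which does not show that they came from separate cultures.

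Tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by material, which left 14990, and libraries were scaled by TMM, with factors from 0.935 to 1.093. All 13 materials entered one quasi-likelihood fit with a mean per material and no block. Residual degrees of freedom were 26, prior degrees of freedom 12.1 and the common coefficient of biological variation 4.6%. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. There were 8 contrasts within material groups, 6 of a group against the mean of the other groups, and an F test over all materials. CPM levels used the TMM-scaled totals, and mean ± SD is over 3 libraries. In contrasts of groups, CPM levels are means over materials.

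Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Of these lists, 35 had at least 5 measured members and were tested with limma's camera on log2 CPM (prior count 3, preset correlation 0.01), with an estimated correlation as an alternative. Adjustment was over the lists within a contrast. With the estimated correlation, 35 of 204 list calls held. Named genes had an adjusted p under 0.05 and a mean of at least 2 CPM. Within groups, all 3 libraries of one material also lay above all 3 of the other, and the 10 largest rises and 10 largest falls were eligible, or 5 and 5 for the coatings against each other. For a group, each of its material means lay outside the range of the others, and 6 and 6 were eligible. Up to 4 members of each called list with the smallest adjusted p, and the 10 genes with the largest F, were also eligible. Values of some single genes are not reported here.

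The procedure was tested on simulated counts with the means and library sizes of the comparison of the gels over 14990 genes. The changed genes, 50 for each fold, were drawn from those with a mean of at least 2 CPM. Of these, 46% were called at 1.2-fold, 88% at 1.5-fold and 100% at 2-fold and 4-fold, and 8 of 175 calls were false. A simulated list of 30 genes shifted 1.3-fold had a camera p of 8.73e-86, and 6 of 200 random lists had a p under 0.05. The simulated genes were drawn independently of each other. These values therefore do not give the error rate for lists of correlated genes.

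Replicate numbers in the labels equal the sequencing run, so they pair libraries by a shared batch, and each run holds 1 library of each material. Deviations from material means correlated with a mean r of 0.052 between libraries of one run and -0.026 between runs, and within the comparisons the correlations of same-numbered libraries ran from -0.08 to 0.33. Between runs 753 genes differed, 2 of them at least 2-fold. The alternatives were the run as a block, DESeq2 1.42.0, size factors of DESeq2 in edgeR, no low-count filter, a test against a 1.5-fold change, only the libraries of the material group, other weights of the groups and each library left out in turn.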

Results

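Gene expression was measured by polyA RNA sequencing in THP-1-derived macrophages on 13 polymeric materials, with 3 libraries per material and 39 in all. THP-1 is a human monocytic leukaemia cell line that phorbol ester turns into adherent macrophage-like cells. The materials formed 6 groups. Polypropylene membranes had pores of 0.6 or 30 µm (PORE-0.6, PORE-30). SIBS surfaces, named as in the labels, were flat or had topography (SIBS-Flat, SIBS-Topo). Silicone was uncoated or carried a coating known only by the code C170 or C301 (CHEM-Unc, CHEM-C170, CHEM-C301), so no chemical structure is given for either. Surgical meshes were of polypropylene or PVDF (MESH-PP, MESH-PVDF). Polyacrylamide gels had a stiffness of 1 or 50 kPa (STIFF-1, STIFF-50). Breast implant shells were smooth or microtextured (SBI-Sm, SBI-Tex). The libraries held 14782148 to 23815163 counted reads, with a median of 19200925. The labels describe 1 experiment with 3 replicates per material, so each p-value measures the spread between libraries of that experiment. Whether these came from separate cultures is not stated. A value after a gene symbol is its log2 fold change ± SE from edgeR's quasi-likelihood fit, and CPM levels are mean ± SD with n = 3. Rose, fell, higher and lower, of a gene, mean a Benjamini-Hochberg adjusted p under 0.05. The largest rises and falls are those of genes that averaged at least 2 CPM and whose replicates did not overlap between the materials compared. A gene list was set against all other genes with limma's camera, once with a preset and once with an estimated correlation between genes. Coordinates are in GRCh38.

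SCD, which encodes stearoyl-CoA desaturase, had the largest F of all genes (702, adjusted p = 1.31e-36). Its level ran from 52.1 ± 3.13 CPM on MESH-PVDF to 1300 ± 216 CPM on uncoated silicone. SCD (ENSG00000099194.6) lies on chromosome 10 from 100347124 to 100364834. FADS2, a fatty acid desaturase, (ENSG00000134824.14, chromosome 11, 61792980 to 61867354) was next, from 3.25 ± 0.378 CPM on MESH-PVDF to 162 ± 19.6 on uncoated silicone. APOE, the apolipoprotein of lipid export (chromosome 19, 44905754 to 44909393), was at 521 ± 72.4 CPM on uncoated silicone and 18.9 ± 1.59 on CHEM-C170. The sterol pathway genes HMGCS1, FDPS, ACAT2 and DHCR7 were also among the leading 10, each highest on uncoated silicone. GDF15, a stress-induced cytokine, was highest on PORE-30 (590 ± 21.2 CPM) and lowest on SBI-Tex (69.8 ± 4.16). CEMIP, a hyaluronan-depolymerising protein, was highest on MESH-PVDF (723 ± 28 CPM) and lowest on SBI-Sm (54.2 ± 5.96). CAPN2, a calpain protease, was highest on CHEM-C170 (611 ± 17.9 CPM) and lowest on MESH-PP (161 ± 3.31). In an F test over all materials, 13054 of 14990 genes tested (87.1%) differed. Of the variance in log2 CPM, summed over genes, 56.4% lay between material groups, 22.3% between materials of a group and 21.2% between replicates. Genes that vary more weigh more in these shares. On the first 2 principal components the gels stood apart from the rest, and the silicones and implant shells lay below 0 on the second, where the SIBS, pore and mesh materials lay above it. SIBS-Flat replicate 3, at 4.82 on the first component, lay away from the other 2 SIBS-Flat libraries at 17.36 and 16.92.

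**Figure D1:**
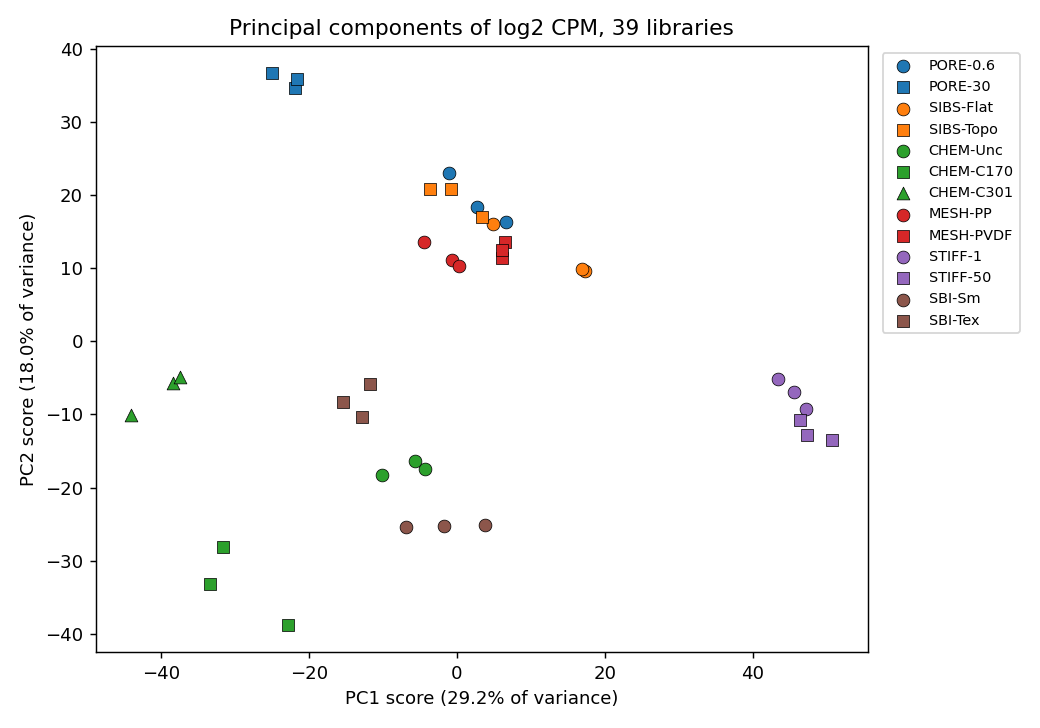
Scores of the 39 libraries on the first principal component (29.2% of the variance) and the second (18% of the variance) of log2 CPM, 1 point per library, coloured by material group with a marker per material. The 6 gel libraries lie above 40 on the first component, and SIBS-Flat replicate 3 lies nearer to SIBS-Topo than the other 2 SIBS-Flat libraries do.

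**Figure D2:**
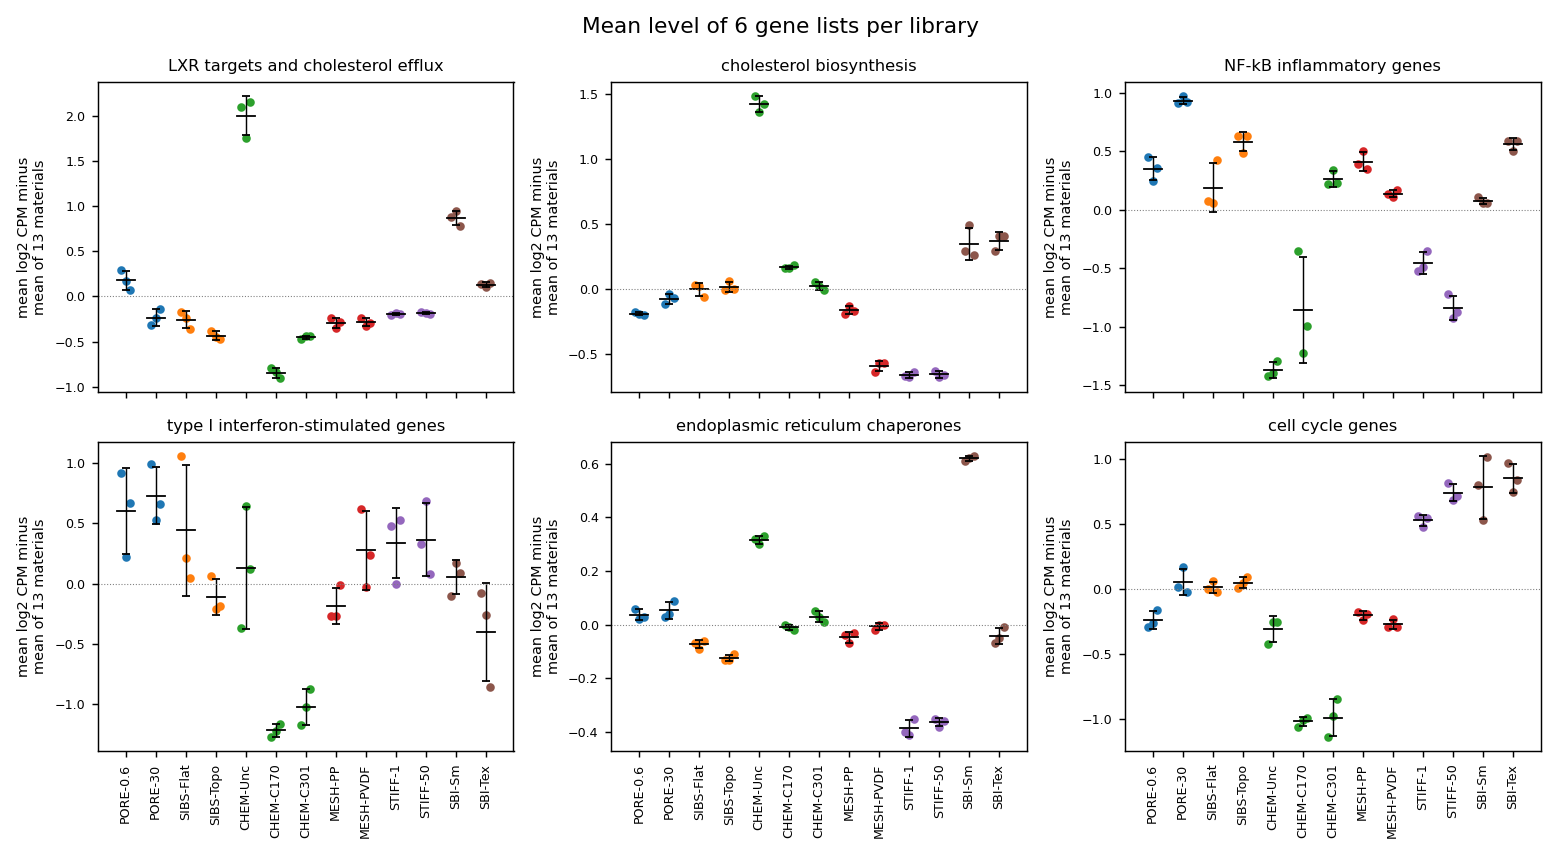
Mean log2 CPM of the genes in 6 lists, centred on the mean over the 13 materials, with 1 point per library and bars for the mean ± SD (n = 3). Genes of LXR and cholesterol biosynthesis are highest on CHEM-Unc, endoplasmic reticulum chaperones on SBI-Sm, and the interferon list spreads between replicates of CHEM-Unc and SIBS-Flat.

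The first comparison within a group asked what pore size changed on polypropylene membranes. On the 30 µm pores, genes of inflammation, oxidative stress and growth factor signalling were higher, and lipid efflux, scavenger receptor and immature myeloid genes were lower. EREG, the EGF family ligand epiregulin (ENSG00000124882.4 on chromosome 4 from 74365143 to 74388751), was at 172 ± 3.01 CPM against 60.8 ± 5.78 CPM on 0.6 µm pores (1.5 ± 0.16, adjusted p = 1.09e-09). COL8A1 (2.03 ± 0.21), a short-chain collagen gene, had the largest rise, and ANKRD1 (1.66 ± 0.24) and the nucleoside transporter gene SLC28A3 (1.53 ± 0.15) rose too. The largest falls included IGFBP5 (-2.71 ± 0.24), the membrane repair gene DYSF (-2.48 ± 0.3), the cholesterol exporter gene ABCG1 (-2.24 ± 0.44) and SORL1 (-2.11 ± 0.18), which was at 12.7 ± 1.47 CPM against 55.6 ± 13.7 CPM on 0.6 µm pores. NCF1B also rose, but it is a near copy of NCF1, so its reads are uncertain. Of the NRF2 targets of the oxidative stress response, 18 of 23 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 2.35e-13, adjusted p = 0.0652 with an estimated correlation). Examples are the ferritin gene FTH1 (0.75 ± 0.06) and the cystine transporter gene SLC7A11 (1.37 ± 0.14). Among NF-kB inflammatory genes 18 of 28 rose and 1 fell (21 and 1 adjusted over the list alone), with camera adjusted p = 5.09e-08, and adjusted p = 0.288 with an estimated correlation. The chemokine genes CXCL3 (1.4 ± 0.18) and CXCL8 (1.11 ± 0.15) and the cytokine genes IL1A (1.09 ± 0.14) and IL1B (0.67 ± 0.09) were among those that rose. In the growth and angiogenic factor list 16 of 27 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 2.64e-05, adjusted p = 0.156 with an estimated correlation), with AREG (1.13 ± 0.14). Matrix and proteolysis genes moved both ways, as 16 of 38 rose and 8 fell (21 and 8 adjusted over the list alone, camera adjusted p = 0.00619, adjusted p = 0.207 with an estimated correlation), and the collagenase gene MMP1 (1.44 ± 0.1) rose while COL4A2 (-1.32 ± 0.12) fell. Scavenger and phagocytic receptors were lower: 3 of 27 rose and 15 fell (3 and 16 adjusted over the list alone, camera adjusted p = 7.98e-05, adjusted p = 0.0711 with an estimated correlation), with TLR4 (-1.2 ± 0.1), MSR1 (-0.88 ± 0.09) and TREM2 (-0.84 ± 0.08). For LXR targets, 0 of 16 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.000655, adjusted p = 0.234 with an estimated correlation), including APOC1 (-0.85 ± 0.1) and APOE (-0.59 ± 0.08). Myeloid progenitor markers were lower as well, since 0 of 14 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 1.16e-05, adjusted p = 0.0652 with an estimated correlation), with the neutrophil elastase gene ELANE (-1.21 ± 0.12) and FLT3 (-1.37 ± 0.17). Mitochondrial genes held 1.74 ± 0.24% of counts on 30 µm pores and 2.28 ± 0.03% on 0.6 µm pores. In all, 3678 genes changed, 1844 higher and 1834 lower, of which 415 changed at least 2-fold. No called list of the 16 held with an estimated correlation, and 253 genes passed when a change of more than 1.5-fold was tested.

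Topography on SIBS was compared with the flat surface. Most of the oxidative stress genes measured were higher on the topography, and some genes of scavenging and of monocytes were lower. The serpin gene SERPINB2 (1.22 ± 0.2), which is ENSG00000197632.9 on chromosome 18 from 63871692 to 63903890, rose from 3.5 ± 1.35 to 8.23 ± 0.863 CPM, and DIRAS2 (1.11 ± 0.16), the receptor gene MAS1 (1.08 ± 0.22) and PCDH17 (0.93 ± 0.18) rose with it. DYSF (-1.13 ± 0.2) fell from 9.86 ± 3.2 to 4.48 ± 1.12 CPM, and the thrombin receptor gene F2R (-1 ± 0.21) fell too. Among NRF2 targets 15 of 23 rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 2.48e-17, and adjusted p = 0.0344 with an estimated correlation. FTH1 (0.49 ± 0.06), SLC7A11 (0.88 ± 0.14) and NQO1 (0.43 ± 0.07) were 3 of those that rose. Some ATF4 stress response genes were higher too, as 8 of 25 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.28e-07, adjusted p = 0.0124 with an estimated correlation). CEBPB (0.43 ± 0.08) and CHAC1 (0.66 ± 0.13) were among them. Of the NF-kB inflammatory genes 14 of 28 rose and 0 fell (21 and 1 adjusted over the list alone, camera adjusted p = 1.66e-12, adjusted p = 0.175 with an estimated correlation). SIBS-Flat replicate 3, at a centred list mean of 0.43, lay nearer to SIBS-Topo (0.49 to 0.63) than to the other SIBS-Flat libraries (0.08 and 0.06). Of matrix genes, 8 of 38 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.094 with an estimated correlation), and the protease genes MMP8 (0.7 ± 0.1), MMP10 (0.68 ± 0.12) and MMP1 (0.56 ± 0.1) were higher. On this list SIBS-Flat replicate 3, at 0.04, lay within SIBS-Topo (0.04 to 0.14) and apart from the other SIBS-Flat libraries (-0.06 and -0.09). For scavenger and phagocytic receptors 1 of 27 rose and 5 fell (1 and 11 adjusted over the list alone, camera adjusted p = 3.9e-05, adjusted p = 0.0445 with an estimated correlation). Among these were TLR4 (-0.47 ± 0.1) and TREM2 (-0.37 ± 0.08). There too SIBS-Flat replicate 3, at -0.07, lay nearer to SIBS-Topo (-0.12 to -0.16) than to the others (0.21 and 0.12). Some monocyte markers were lower, as 0 of 15 rose and 3 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.0445 with an estimated correlation), with VCAN (-0.82 ± 0.16) and the fractalkine receptor gene CX3CR1 (-0.65 ± 0.13). The transcription factor genes KLF4 (-0.58 ± 0.09) and PPARG (-0.44 ± 0.08) fell. Type I interferon-stimulated genes had some of the largest falls: 0 of 35 rose and 5 fell (0 and 22 adjusted over the list alone, camera adjusted p = 1.24e-09, adjusted p = 0.327 with an estimated correlation), among them IFIT2 (-1.86 ± 0.49) and HERC5 (-1.37 ± 0.34). Much of this came from SIBS-Flat replicate 1, without which IFIT2 was at -0.76 (adjusted p = 0.628) and HERC5 at -0.59 (adjusted p = 0.534). Without SIBS-Topo replicate 3 both had an adjusted p of 0.11, but the values stayed at -1.67 and -1.16. Mitochondrial genes held 2.27 ± 0.17% of counts on SIBS-Flat and 1.93 ± 0.02% on SIBS-Topo. Altogether 866 genes changed, 455 higher and 411 lower, with 39 changed at least 2-fold. The count was 284, 388 and 1316 without SIBS-Flat replicate 1, 2 or 3, and 353 and 418 without SIBS-Topo replicate 1 or 3. Tested against a 1.5-fold change, edgeR passed 0 genes, with 138 at an unadjusted p under 0.05.

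Both coatings of silicone were set against the uncoated surface. On C170, lipid efflux and cholesterol synthesis genes were far lower, and oxidative stress genes and some chemokine and protease genes were higher. The cholesterol exporter gene ABCG1 (-8.55 ± 0.37), which is ENSG00000160179.18 on chromosome 21 from 42199689 to 42297244, fell from 65 ± 18.9 to 0.175 ± 0.163 CPM, and APOC1 (-5.61 ± 0.13) from 208 ± 46.7 to 4.27 ± 0.266 CPM. APOE (-4.79 ± 0.1), SCD (-3.76 ± 0.09) and the protease gene ADAMTS1 (-4.33 ± 0.11), which was at 101 ± 0.8 CPM without a coating and 5.02 ± 0.427 CPM on C170, fell too. BMP10 (3.72 ± 0.28) had the largest rise, from 0.316 ± 0.0568 to 4.32 ± 0.0642 CPM, ahead of the stromelysin gene MMP10 (2.85 ± 0.12) and the platelet chemokine gene PPBP (2.54 ± 0.15). Of the LXR targets, 0 of 16 rose and 15 fell (0 and 16 adjusted over the list alone, camera adjusted p = 5.48e-24, adjusted p = 0.000427 with an estimated correlation). In the cholesterol biosynthesis list, 1 of 24 rose and 22 fell (1 and 22 adjusted over the list alone, camera adjusted p = 3.42e-25, adjusted p = 0.00336 with an estimated correlation). FDPS (-1.82 ± 0.05) and HMGCS1 (-2.1 ± 0.06) were among them. Endoplasmic reticulum chaperones were lower by less, as 2 of 21 rose and 17 fell (2 and 17 adjusted over the list alone, camera adjusted p = 2.08e-10, adjusted p = 0.00546 with an estimated correlation). Among these were CALR (-0.48 ± 0.03) and HSP90B1 (-0.59 ± 0.04). NRF2 targets were higher: 16 of 23 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 8.54e-12, adjusted p = 0.0869 with an estimated correlation), with SLC7A11 (2.08 ± 0.14), NQO1 (1.14 ± 0.07) and FTH1 (0.99 ± 0.06). NF-kB inflammatory genes went both ways, as 17 of 28 rose and 5 fell (17 and 6 adjusted over the list alone, camera adjusted p = 0.00582, adjusted p = 0.672 with an estimated correlation), and CXCL3 (2.26 ± 0.21) rose while CCL5 (-0.81 ± 0.07) fell. CHEM-C170 replicate 1 stood apart, with a centred list mean of -0.35 against -1.22 and -0.99 in the others and -1.42 to -1.29 on uncoated silicone. Without it the adjusted p of that list was 0.0694. Of cell cycle genes, 2 of 35 rose and 25 fell (2 and 26 adjusted over the list alone, camera adjusted p = 7.85e-08, adjusted p = 0.24 with an estimated correlation). MKI67 (-1.52 ± 0.18) and RRM2 (-1.56 ± 0.14) were among them. Type I interferon-stimulated genes were lower too, since 0 of 35 rose and 34 fell (0 and 34 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.527 with an estimated correlation). Among these were OAS3 (-1.63 ± 0.23) and MX1 (-3.78 ± 0.66). Mean log2 CPM of that list was 2.95, 3.96 and 3.44 in the CHEM-Unc libraries. The share of counts on mitochondrial genes was 2.28 ± 0.56% on C170, 2.91 ± 0.31% on C301 and 3.2 ± 0.07% on uncoated silicone. The comparison called 6213 genes, 3092 higher and 3121 lower, and 955 when a change of more than 1.5-fold was tested.

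On C301, lipid genes fell as well, and most of the inflammatory genes measured rose. ABCG1 (-6.98 ± 0.31) fell to 0.496 ± 0.189 CPM, SCD (-3.88 ± 0.09) to 88.3 ± 4.42 CPM and FADS2 (-4.12 ± 0.1) from 162 ± 19.6 to 9.31 ± 0.944 CPM. The neutrophil chemokine genes CXCL3 (3.6 ± 0.21), CXCL1 (3.46 ± 0.2), CXCL2 (3.71 ± 0.23) and CXCL5 (3.89 ± 0.28) rose, with CXCL3 (ENSG00000163734.4 on chromosome 4 from 74036589 to 74038807) going from 20.2 ± 0.482 to 245 ± 18.2 CPM. The plasminogen activator inhibitor gene SERPINB2 (3.93 ± 0.24) rose as well. CCL4, TREML3P, CCL4L2 and CCL3L3 had large rises too, but each is a pseudogene or has a near copy, so their reads are uncertain. Of NF-kB inflammatory genes 25 of 28 rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 1.02e-17, adjusted p = 0.129 with an estimated correlation), NFKBIA (1.82 ± 0.1) and CXCL8 (2.86 ± 0.16) included. Of LXR targets, 0 of 16 rose and 16 fell (0 and 16 adjusted over the list alone, camera adjusted p = 8.39e-21, adjusted p = 0.00115 with an estimated correlation), and for cholesterol biosynthesis 1 of 24 rose and 23 fell (1 and 23 adjusted over the list alone, camera adjusted p = 2.6e-26, adjusted p = 0.00261 with an estimated correlation). ACAT2 (-3.12 ± 0.08) and DHCR7 (-2.66 ± 0.07) were among them. NRF2 targets were higher, as 22 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 6.4e-18, adjusted p = 0.0167 with an estimated correlation). Among these were SLC7A11 (2.88 ± 0.15) and NQO1 (1.46 ± 0.07). Some alternative activation markers were lower: 0 of 23 rose and 11 fell (0 and 11 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.0333 with an estimated correlation), with the interleukin 1 receptor antagonist gene IL1RN (-1.58 ± 0.09), PPARG (-1.12 ± 0.09) and MAF (-1.18 ± 0.1). For endoplasmic reticulum chaperones, 1 of 21 rose and 17 fell (1 and 17 adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.0161 with an estimated correlation). Matrix genes moved in both directions, as 19 of 38 rose and 10 fell (19 and 12 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.208 with an estimated correlation), among them MMP1 (1.93 ± 0.1), THBS1 (1.91 ± 0.11) and TIMP3 (-1.33 ± 0.07). Of the interferon-stimulated genes 0 of 35 rose and 31 fell (0 and 32 adjusted over the list alone, camera adjusted p = 2.07e-07, adjusted p = 0.41 with an estimated correlation), and of cell cycle genes 1 of 35 rose and 24 fell (2 and 26 adjusted over the list alone, camera adjusted p = 3.99e-07, adjusted p = 0.19 with an estimated correlation). In total 6421 genes changed, 3193 higher and 3228 lower, and 1091 passed against a 1.5-fold change.

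Set against each other, the coatings differed in inflammatory genes and growth factors, which were higher on C301, and in granule protein genes of immature myeloid cells, which were lower on it. SERPINB2 (2.48 ± 0.19) was at 15.3 ± 0.894 CPM on C301 and 2.78 ± 1.27 CPM on C170, and WNT5A (2.32 ± 0.24), the cytokine subunit gene EBI3 (2.19 ± 0.14) and the Notch ligand gene DLL4 (2.1 ± 0.18) were also higher. BMP10 (-2.27 ± 0.23), the collagenase gene MMP13 (-2.05 ± 0.25) and the potassium channel gene KCNQ3 (-1.87 ± 0.11) were lower, KCNQ3 at 19.6 ± 0.733 CPM against 71.5 ± 15.3 CPM. Of the NF-kB inflammatory genes 25 of 28 rose and 0 fell (26 and 0 adjusted over the list alone, camera adjusted p = 4.39e-26, adjusted p = 0.0623 with an estimated correlation), with IL1B (1.28 ± 0.1) and CCL20 (1.81 ± 0.15). CHEM-C170 replicate 1, at a centred list mean of -0.35, lay nearer to C301 (0.22 to 0.34) than the other C170 libraries did. Of growth and angiogenic factors, 19 of 27 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 5.68e-10, adjusted p = 0.0425 with an estimated correlation). BMP6 (1.28 ± 0.14) and LIF (1.69 ± 0.17) were among them. For myeloid progenitor markers 0 of 14 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 5.56e-07, adjusted p = 0.0425 with an estimated correlation), with the granule protease genes CTSG (-1.13 ± 0.1), ELANE (-0.92 ± 0.08) and PRTN3 (-0.98 ± 0.11). Actin cytoskeleton genes were lower on C301, where 1 of 30 rose and 19 fell (1 and 19 adjusted over the list alone, camera adjusted p = 2.02e-08, adjusted p = 0.112 with an estimated correlation). Among these were CNN2 (-0.85 ± 0.07) and VCL (-0.57 ± 0.06). Some LXR targets were higher on C301 than on C170, as 7 of 16 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.246 with an estimated correlation). APOE (1.21 ± 0.1) and ABCA1 (1.21 ± 0.14) were among them. These differences came to 3747 genes, 1892 higher and 1855 lower on C301, and 199 against a 1.5-fold change. Across the 14990 genes, which are not independent replicates, the log2 fold changes of the coatings against uncoated silicone correlated with r = 0.762 (rho = 0.704). Within sequencing runs 1, 2 and 3, r was 0.78, 0.656 and 0.745. Unchanged groups simulated against 3 shared, simulated uncoated libraries gave r from 0.488 to 0.538 in 20 simulations, mean 0.515. The observed covariance was 0.254 and the simulated 0.027, a difference of 0.227. Both coatings raised 2081 genes, where independent lists would share 659, and both lowered 2154, where they would share 672. In the simulations, which leave out real effects, 0 genes were called alike in both by edgeR. Another 154 genes changed in opposite directions. With 3 uncoated libraries the controls cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls.

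Meshes of polypropylene and PVDF differed in cholesterol synthesis. Of cholesterol biosynthesis genes, 20 of 24 rose and 0 fell (22 and 1 adjusted over the list alone) on polypropylene (camera adjusted p = 1.27e-39, adjusted p = 0.000357 with an estimated correlation). Among them were the synthase gene HMGCS1 (0.55 ± 0.06), which is ENSG00000112972.15 on chromosome 5 from 43289395 to 43313512, and FDPS (0.46 ± 0.05). The desaturase gene FADS2 (1.17 ± 0.17) rose from 3.25 ± 0.378 to 7.33 ± 1.21 CPM and the calgranulin gene S100A9 (1.06 ± 0.16) from 4.78 ± 0.653 to 10.1 ± 0.592 CPM. RASAL1 (1.63 ± 0.18) had the largest rise, and the neuronal pentraxin gene NPTX1 (1.35 ± 0.12) rose from 40.8 ± 1.8 to 104 ± 2.02 CPM. NCF1 (1 ± 0.1), a subunit of the NADPH oxidase, rose with its pseudogenes NCF1B and NCF1C, which may split the same reads, so all 3 are uncertain. The largest falls were DYSF (-1.07 ± 0.19), CEMIP (-0.95 ± 0.07) from 723 ± 28 to 374 ± 12.1 CPM, and IGFBP5 (-0.88 ± 0.13). In the NF-kB list 7 of 28 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.73e-06, adjusted p = 0.506 with an estimated correlation). Among these were TNF (0.54 ± 0.11) and PTGS2 (0.45 ± 0.1). The growth factor genes VEGFA (0.47 ± 0.08) and FGF2 (0.4 ± 0.06) rose. Mitochondrial genes held 2.47 ± 0.22% of counts on MESH-PP and 2.13 ± 0.02% on MESH-PVDF. The comparison called 518 genes, 316 higher and 202 lower, with 14 changed at least 2-fold and 4 past a 1.5-fold test. It called 965 when the 6 mesh libraries were fitted alone. Leaving out MESH-PP replicate 2 gave 267 genes, and MESH-PVDF replicate 1, 2 or 3 gave 333, 338 and 299.

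Gels of 50 and 1 kPa gave the fewest changes of the 8 comparisons within groups. On the stiffer gel, some inflammatory and immediate early genes were lower. The cyclooxygenase gene PTGS2 (-0.78 ± 0.13), which is ENSG00000073756.12 on chromosome 1 from 186671791 to 186680427, fell from 9.51 ± 0.514 to 5.54 ± 0.364 CPM and CSF1 (-0.61 ± 0.09), the macrophage colony-stimulating factor gene, from 54.1 ± 1.72 to 35.5 ± 2.35 CPM. HIVEP2 (-1 ± 0.16), GADD45B (-0.61 ± 0.09), the stress transcription factor gene ATF3 (-0.53 ± 0.07) and the kinase gene SGK1 (-0.38 ± 0.05) fell as well. Of immediate early genes 0 of 30 rose and 6 fell (0 and 16 adjusted over the list alone, camera adjusted p = 2.4e-18, adjusted p = 0.00137 with an estimated correlation), and of the ATF4 list 0 of 25 rose and 2 fell (0 and 10 adjusted over the list alone, camera adjusted p = 2.6e-09, adjusted p = 0.00137 with an estimated correlation). Among NF-kB inflammatory genes 0 of 28 rose and 4 fell (0 and 21 adjusted over the list alone, camera adjusted p = 9.1e-19, adjusted p = 0.108 with an estimated correlation). The chemokine gene CXCL8 (-0.68 ± 0.15) fell from 1350 ± 143 to 843 ± 89 CPM, but lost its call without STIFF-1 replicate 2 (-0.67, adjusted p = 0.0842) or 3 (-0.61, adjusted p = 0.214) or STIFF-50 replicate 2 (-0.61, adjusted p = 0.232) or 3 (-0.68, adjusted p = 0.126), with little change in the value. The surface glycoprotein gene CDCP1 (0.67 ± 0.13) had the largest of the 7 rises, and was not called without STIFF-1 replicate 3 (0.62, adjusted p = 0.122) or STIFF-50 replicate 2 (0.65, adjusted p = 0.0534), again with little change in the value. In all, 65 genes changed, 7 higher and 58 lower, with 1374 at an unadjusted p under 0.05. With the sequencing run as a block the count was 101, without a low-count filter 247 and with the gels fitted alone 125. It was 13 without STIFF-1 replicate 3, and 20 and 28 without STIFF-50 replicate 2 or 3. Against a 1.5-fold change edgeR passed 0 genes, with 48 at an unadjusted p under 0.05.

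Textured and smooth breast implant shells differed in stress, lipid and matrix genes. On the textured shell every one of the endoplasmic reticulum chaperones was lower, as 0 of 21 rose and 21 fell (0 and 21 adjusted over the list alone, camera adjusted p = 9.35e-35, adjusted p = 1.82e-06 with an estimated correlation). HSPA5 (-0.99 ± 0.03), the chaperone BiP (ENSG00000044574.8 on chromosome 9 from 125234853 to 125241330), and HYOU1 (-0.87 ± 0.04) were among them. The inducible heat shock gene HSPA6 (-4.04 ± 0.17), which is ENSG00000173110.8 on chromosome 1 from 161524540 to 161526910, had the largest fall, from 23.5 ± 2.08 to 1.44 ± 0.401 CPM, and VWA5A (-3.6 ± 0.12) fell from 36 ± 5.2 to 2.97 ± 0.101 CPM. The matrix crosslinking enzyme gene LOX (-2.87 ± 0.16) and the peptidase gene DPP4 (-3.16 ± 0.24) fell too. NOS2 (2.46 ± 0.19), the inducible nitric oxide synthase gene, rose from 1.74 ± 0.618 to 9.31 ± 1.18 CPM, the hormone gene STC1 (2.28 ± 0.17) from 22.5 ± 10.9 to 107 ± 3.7 CPM and the elastase gene MMP12 (2.35 ± 0.17) from 3.99 ± 1.22 to 20 ± 0.637 CPM. The chemokine gene CXCL5 (2.45 ± 0.22) rose too. In the ATF4 stress response 1 of 25 rose and 17 fell (1 and 17 adjusted over the list alone, camera adjusted p = 5.86e-11, adjusted p = 0.000459 with an estimated correlation). TRIB3 (-1.56 ± 0.06) and DDIT3 (-1.37 ± 0.05) were among them. NRF2 targets were lower, as 1 of 23 rose and 20 fell (1 and 20 adjusted over the list alone, camera adjusted p = 1.43e-12, adjusted p = 0.0331 with an estimated correlation). Among these were GCLM (-1.37 ± 0.1) and HMOX1 (-0.82 ± 0.08). For heat shock genes 0 of 17 rose and 10 fell (0 and 11 adjusted over the list alone, camera adjusted p = 2.07e-06, adjusted p = 0.0124 with an estimated correlation), where the near-identical HSPA1A and HSPA1B are uncertain. Of PPAR targets and lipid storage genes 2 of 17 rose and 12 fell (2 and 12 adjusted over the list alone, camera adjusted p = 1.16e-07, adjusted p = 0.00542 with an estimated correlation), with the lipid droplet gene PLIN2 (-1.17 ± 0.06), CD36 (-1.79 ± 0.11) and FABP4 (-1.73 ± 0.11). LXR targets were lower: 1 of 16 rose and 12 fell (2 and 12 adjusted over the list alone, camera adjusted p = 1.16e-07, adjusted p = 0.0331 with an estimated correlation). APOE (-1.51 ± 0.09) and SCD (-0.78 ± 0.08) were among them. Integrin and focal adhesion genes were higher, as 23 of 34 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 9.55e-10, adjusted p = 0.0124 with an estimated correlation), among them ITGA1 (0.94 ± 0.09) and ITGB2 (0.47 ± 0.04). Of matrix genes, 20 of 38 rose and 4 fell (21 and 6 adjusted over the list alone, camera adjusted p = 2.07e-06, adjusted p = 0.0148 with an estimated correlation), and PLAU (1.51 ± 0.09) and MMP1 (1.48 ± 0.11) rose. Among NF-kB inflammatory genes 18 of 28 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 1.85e-05, adjusted p = 0.35 with an estimated correlation). Among these were PTGS2 (1.22 ± 0.1) and IL1B (0.99 ± 0.1). The comparison called 4505 genes, 2361 higher and 2144 lower, with 493 changed at least 2-fold. Tested against a 1.5-fold change, 407 passed.

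Each material group was then compared with the other 5 groups, weighted alike. These values are averages over the materials of a group, and a single material can lie within the range of the other groups. List means are mean log2 CPM, centred over the 13 materials. The groups also differed in handling, which these contrasts cannot separate from the material: per the labels, implant shells were in 12-well plates and lysed in 1200 µL, meshes were seeded more densely with lysates of 2 wells pooled, and gels were lysed 2 times. In the plot of genes changed per comparison, the gels and the silicones have the longest bars of the 6 groups.

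**Figure D3:**
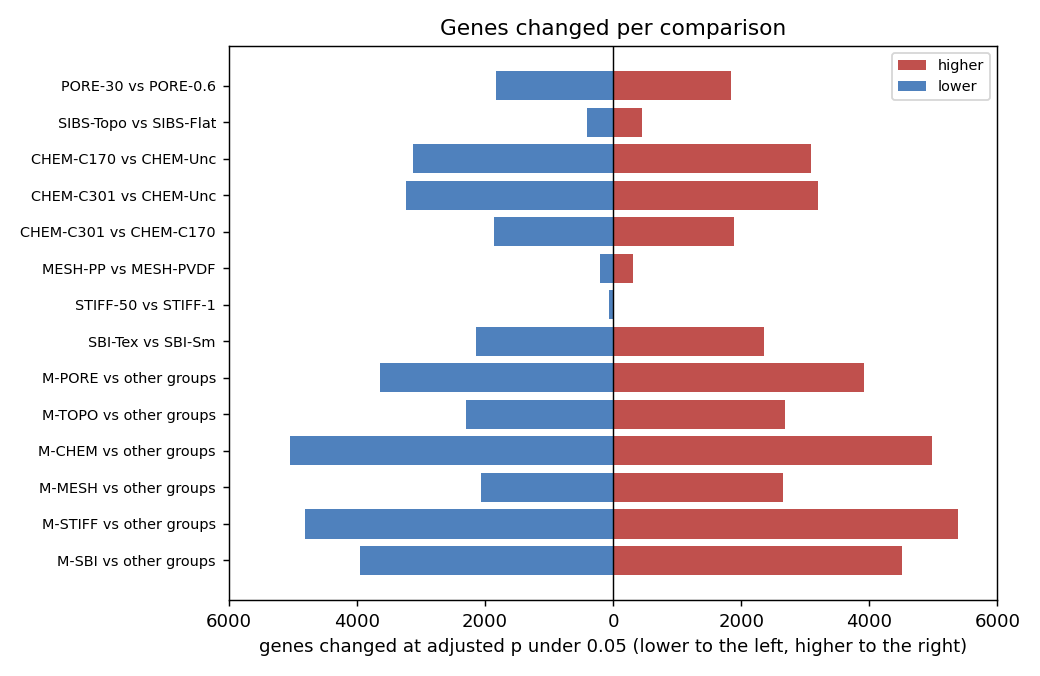
Number of genes changed in each of 14 comparisons at an edgeR adjusted p under 0.05, lower genes to the left of 0 and higher genes to the right. The bars run from 65 genes between the gels to 10195 between the gels and the other groups.

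Gels and silicones gave the most changed genes of the 6 groups. The gels led, at 10195 against 10019, but not without any 1 of the gel libraries, with 9634 to 9940 for the gels and 9986 to 10021 for the silicones. The purinergic receptor gene P2RY12 (3.77 ± 0.2), DYSF (3.37 ± 0.08), IGFBP5 (2.9 ± 0.07) and CCL21 (2.87 ± 0.14) were highest on gels, and DYSF averaged 35.7 CPM over the gels and 4.59 CPM over the other materials. The cell fusion gene DCSTAMP (-2.65 ± 0.1) was lower, at 13 against 96.1 CPM, as were PPBP (-2.73 ± 0.14), COL8A1 (-2.93 ± 0.19) and the gap junction gene GJA5 (-3.01 ± 0.2). Of endoplasmic reticulum chaperones, 0 of 21 rose and 20 fell (0 and 20 adjusted over the list alone, camera adjusted p = 7.94e-13, adjusted p = 0.00421 with an estimated correlation). HSPA5 (-0.6 ± 0.02) and HYOU1 (-0.58 ± 0.02) were among them. Of cholesterol biosynthesis genes, 0 of 24 rose and 23 fell (0 and 23 adjusted over the list alone, camera adjusted p = 1.93e-14, adjusted p = 0.0516 with an estimated correlation). INSIG1 (-1.23 ± 0.04) was among them. Cell cycle genes were higher, as 35 of 35 rose and 0 fell (35 and 0 adjusted over the list alone, camera adjusted p = 3.56e-10, adjusted p = 0.101 with an estimated correlation), and so were ribosomal protein genes, as 36 of 36 rose and 0 fell (36 and 0 adjusted over the list alone, camera adjusted p = 1.2e-12, adjusted p = 0.173 with an estimated correlation). Of NF-kB inflammatory genes 1 of 28 rose and 26 fell (1 and 26 adjusted over the list alone, camera adjusted p = 3.66e-07, adjusted p = 0.271 with an estimated correlation). CXCL8 (-1.93 ± 0.1) and IL1A (-2.14 ± 0.12) were among them. The NF-kB list mean was -0.45 on STIFF-1 and -0.84 on STIFF-50, within the range of the other groups, where uncoated silicone was at -1.37. Cell cycle list means were 0.53 on STIFF-1 and 0.74 on STIFF-50, below the smooth shell at 0.78 and the textured one at 0.85. Growth factor genes were lower in most cases, as 4 of 27 rose and 20 fell (4 and 20 adjusted over the list alone, camera adjusted p = 7.47e-05, adjusted p = 0.173 with an estimated correlation). Among these were AREG (-2.34 ± 0.1) and EREG (-2.37 ± 0.12). The growth factor list was at -0.5 on STIFF-1 and -0.75 on STIFF-50, with C170 also at -0.5. Scavenger receptors were higher, as 17 of 27 rose and 6 fell (17 and 6 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.239 with an estimated correlation), including OLR1 (1.84 ± 0.07) and CD36 (1.4 ± 0.05). On the chaperone, cholesterol biosynthesis, ribosomal protein and scavenger lists the means of both gels lay outside the range of the other materials. The count was 10195 genes, 5390 higher and 4805 lower, of which 1568 passed against a 1.5-fold change.

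On silicones, cell cycle and ribosomal protein genes were lower than on the other groups. The lysosomal membrane gene LAMP3 (-3.26 ± 0.13) was at 1.02 against 8.01 CPM, and the adhesion molecule gene VCAM1 (-3.1 ± 0.2) and CDC25A (-2.25 ± 0.11) were lower too. DCSTAMP (1.6 ± 0.06) was at 152 against 62.6 CPM, and the calcium pump gene ATP2B4 (1.58 ± 0.05) and the acyltransferase gene GPAT3 (1.66 ± 0.04) were higher. For cell cycle genes 1 of 35 rose and 34 fell (1 and 34 adjusted over the list alone, camera adjusted p = 4.3e-15, adjusted p = 0.0698 with an estimated correlation). MCM2 (-0.86 ± 0.04) and TYMS (-1.81 ± 0.09) were among them. The coatings carried most of this, with list means of -1.02 on C170 and -0.99 on C301. Uncoated silicone, at -0.31 ± 0.1, was near MESH-PVDF at -0.27 ± 0.04. Of ribosomal protein genes, 0 of 36 rose and 36 fell (0 and 36 adjusted over the list alone, camera adjusted p = 2.08e-17, adjusted p = 0.135 with an estimated correlation). Of NF-kB inflammatory genes 0 of 28 rose and 25 fell (0 and 25 adjusted over the list alone, camera adjusted p = 1.24e-10, adjusted p = 0.251 with an estimated correlation). Among these were TNF (-1.73 ± 0.06) and CCL20 (-1.85 ± 0.07). C301 did not share this: the NF-kB list mean was -1.37 on uncoated silicone, -0.85 on C170 and 0.26 on C301, the last within the range of the other groups. Interferon-stimulated genes were lower on average, as 0 of 35 rose and 33 fell (0 and 33 adjusted over the list alone, camera adjusted p = 4.42e-07, adjusted p = 0.388 with an estimated correlation), with list means of 0.13 on uncoated silicone, -1.22 on C170 and -1.02 on C301. Cholesterol biosynthesis genes were higher on average, as 23 of 24 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 7.56e-15, adjusted p = 0.0698 with an estimated correlation). Uncoated silicone carried most of this, with a list mean of 1.42 against 0.17 on C170 and 0.02 on C301, both below the shells at 0.35 and 0.37. Myeloid progenitor markers were higher in most cases: 11 of 14 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.155 with an estimated correlation). Among these were ELANE (1.21 ± 0.04) and AZU1 (1.04 ± 0.04). List means were 0.37 on uncoated silicone, 0.59 on C170 and 0.02 on C301, the last within the range of the other groups. The contrast called 10019 genes, 4984 higher and 5035 lower, and 958 against a 1.5-fold change. No called list held with an estimated correlation.

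On implant shells, cell cycle and ATF4 stress response genes were higher. The calgranulin genes S100A8 (3.23 ± 0.15) and S100A9 (2.25 ± 0.06) were higher, S100A9 at 32.6 against 7.09 CPM. HSPA6 (3.59 ± 0.16) had the largest rise, though it differed between the shells as already given. The basement membrane collagen genes COL4A1 (-2.02 ± 0.1) and COL4A2 (-2.11 ± 0.08), the IgE receptor gene FCER2 (-2.25 ± 0.18) and GLDN (-3.01 ± 0.09) were lower. Of endoplasmic reticulum chaperones, 21 of 21 rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 2.22e-14, adjusted p = 0.00103 with an estimated correlation), as an average of unlike shells. The list mean was 0.62 on the smooth shell and -0.04 on the textured one, which lies within the range of the other groups. In the ATF4 list 22 of 25 rose and 1 fell (22 and 2 adjusted over the list alone, camera adjusted p = 2.88e-10, adjusted p = 0.00103 with an estimated correlation), with TRIB3 (1.13 ± 0.03) and the serine synthesis gene PHGDH (1.26 ± 0.05). Of cell cycle genes 34 of 35 rose and 0 fell (34 and 0 adjusted over the list alone, camera adjusted p = 1.25e-15, adjusted p = 0.0374 with an estimated correlation). CDC6 (1.58 ± 0.06) and TYMS (1.59 ± 0.07) were among them. NRF2 targets were higher on average: 20 of 23 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 5.05e-11, adjusted p = 0.0915 with an estimated correlation), with list means of 0.76 on the smooth shell and 0.16 on the textured one. Of LXR targets, 12 of 16 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000365, adjusted p = 0.165 with an estimated correlation), with FADS2 (2.3 ± 0.05) and SCD (1.55 ± 0.04) and list means of 0.87 and 0.13, and for cholesterol biosynthesis 23 of 24 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 3.21e-12, adjusted p = 0.0591 with an estimated correlation). Ribosomal protein genes were lower, as 0 of 36 rose and 36 fell (0 and 36 adjusted over the list alone, camera adjusted p = 5.29e-14, adjusted p = 0.115 with an estimated correlation). The contrast called 8464 genes, 4514 higher and 3950 lower, and 938 against a 1.5-fold change.

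On the pore membranes, inflammatory and interferon genes were on average higher and monocyte markers lower. The vitamin A transporter gene STRA6 (1.8 ± 0.1), the sialoadhesin gene SIGLEC1 (1.79 ± 0.17) and IFI44L (1.99 ± 0.23) were higher, SIGLEC1 at 16.2 against 5.17 CPM. The potassium channel genes KCNQ3 (-1.7 ± 0.08) and KCNQ1 (-1.58 ± 0.09) and NCALD (-1.83 ± 0.15) were lower. All NF-kB inflammatory genes measured were higher, as 28 of 28 rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 1.18e-13, adjusted p = 0.227 with an estimated correlation), IL1B (1.12 ± 0.05) and EBI3 (1.16 ± 0.06) among them. The list mean was 0.93 on PORE-30 and 0.35 on PORE-0.6, the latter within the range of the other groups. For interferon-stimulated genes 34 of 35 rose and 0 fell (35 and 0 adjusted over the list alone, camera adjusted p = 3.53e-08, adjusted p = 0.408 with an estimated correlation). Among these were IFI6 (1.32 ± 0.08) and IFI44 (1.47 ± 0.16). Centred list means were 0.92, 0.22 and 0.67 in the PORE-0.6 libraries and 0.99, 0.53 and 0.66 in the PORE-30 libraries, while SIBS-Flat replicate 1 was at 1.06. Monocyte markers were lower, as 0 of 15 rose and 11 fell (1 and 11 adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.0232 with an estimated correlation), with the LPS co-receptor gene CD14 (-1.03 ± 0.07) and VCAN (-1.81 ± 0.13). Their mean was -0.61 on PORE-30 and -0.34 on PORE-0.6, with SIBS-Topo at -0.37. Of growth factors, 18 of 27 rose and 3 fell (18 and 3 adjusted over the list alone, camera adjusted p = 2.82e-05, adjusted p = 0.197 with an estimated correlation). LIF (1.6 ± 0.07) and VEGFA (0.8 ± 0.04) were among them. The growth factor list was at 0.62 on PORE-30 and 0.15 on PORE-0.6, the latter within the range of the other groups. The contrast called 7561 genes, 3925 higher and 3636 lower, and 383 against a 1.5-fold change.

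On the SIBS surfaces inflammatory genes were on average higher and LXR target and chaperone genes lower than on the other groups. The plasminogen activator gene PLAT (1.67 ± 0.15), LAMP3 (1.47 ± 0.08) and the creatine kinase gene CKB (1.04 ± 0.04) were higher, CKB at 59.3 against 29.7 CPM, and MYADM (-1.13 ± 0.1), ATF3 (-0.69 ± 0.04) and HEYL (-0.73 ± 0.1) were lower. Of endoplasmic reticulum chaperones 0 of 21 rose and 14 fell (0 and 14 adjusted over the list alone, camera adjusted p = 1.92e-08, adjusted p = 0.0483 with an estimated correlation), with HERPUD1 (-0.25 ± 0.02). The list mean was -0.07 on SIBS-Flat and -0.12 on SIBS-Topo, between STIFF-1 at -0.39 and SBI-Sm at 0.62. NF-kB inflammatory genes were higher, as 24 of 28 rose and 0 fell (26 and 0 adjusted over the list alone, camera adjusted p = 1.3e-11, adjusted p = 0.162 with an estimated correlation). Among these were TNF (0.77 ± 0.06) and IL1B (0.66 ± 0.05). The NF-kB list was at 0.19 on SIBS-Flat and 0.59 on SIBS-Topo, between uncoated silicone at -1.37 and PORE-30 at 0.93. Of lysosome genes, 1 of 35 rose and 22 fell (1 and 24 adjusted over the list alone, camera adjusted p = 2.21e-09, adjusted p = 0.0906 with an estimated correlation). CTSB (-0.24 ± 0.02) was among them. The lysosome list was at -0.11 on SIBS-Flat, -0.09 on SIBS-Topo and -0.11 on SBI-Tex. LXR targets were lower: 2 of 16 rose and 12 fell (3 and 12 adjusted over the list alone, camera adjusted p = 3.44e-07, adjusted p = 0.0906 with an estimated correlation), with APOE (-0.56 ± 0.05). Their mean was -0.26 on SIBS-Flat and -0.43 on SIBS-Topo, between C170 at -0.84 and uncoated silicone at 2. SIBS-Flat was near PORE-30 at -0.24 and MESH-PP and MESH-PVDF, each at -0.29, and SIBS-Topo was near C301 at -0.45. Altogether 4977 genes changed, 2688 higher and 2289 lower, 59 changed at least 2-fold, and 22 passed against a 1.5-fold change.

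Meshes had on average lower cholesterol synthesis and higher matrix genes than the other groups. The phosphatase gene ACP3 (0.87 ± 0.03), the kinase gene NEK10 (0.62 ± 0.04) and the receptor gene EGFR (0.52 ± 0.07) were higher, ACP3 at 76.3 against 43.1 CPM, and HSPA6 (-1.92 ± 0.26), CAPN2 (-0.65 ± 0.03) and the receptor gene LILRA6 (-1.05 ± 0.15) were lower. Of cholesterol biosynthesis genes, 0 of 24 rose and 23 fell (0 and 23 adjusted over the list alone, camera adjusted p = 4.92e-26, adjusted p = 0.00556 with an estimated correlation). Among these were FDPS (-0.47 ± 0.03) and DHCR7 (-0.77 ± 0.05). The list mean was -0.16 on MESH-PP and -0.59 on MESH-PVDF, between STIFF-1 at -0.67 and uncoated silicone at 1.42. For matrix and proteolysis genes 24 of 38 rose and 4 fell (25 and 4 adjusted over the list alone, camera adjusted p = 3.12e-08, adjusted p = 0.00975 with an estimated correlation), with TIMP1 (0.43 ± 0.03) and the osteopontin gene SPP1 (0.57 ± 0.05). That list was at 0.19 on MESH-PP and 0.17 on MESH-PVDF, between STIFF-50 at -0.33 and C301 at 0.29. In the ATF4 list 2 of 25 rose and 10 fell (2 and 11 adjusted over the list alone, camera adjusted p = 7.92e-05, adjusted p = 0.0489 with an estimated correlation), with TRIB3 (-0.46 ± 0.04). Its mean was -0.06 on MESH-PP and -0.14 on MESH-PVDF, between STIFF-50 at -0.18 and SBI-Sm at 0.69. MESH-PP was near STIFF-1 at -0.05, and uncoated silicone was at -0.14 like MESH-PVDF. Cell cycle genes were lower, as 0 of 35 rose and 28 fell (1 and 29 adjusted over the list alone, camera adjusted p = 7.21e-12, adjusted p = 0.0829 with an estimated correlation). TPX2 (-0.71 ± 0.07) and CDC20 (-0.72 ± 0.08) were among them. Cell cycle list means were -0.2 on MESH-PP and -0.27 on MESH-PVDF, within the range of the other groups. The contrast called 4708 genes, 2655 higher and 2053 lower, and 23 against a 1.5-fold change.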

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

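The tests of length and GC bias and of sequencing depth were set before their results were seen, and the tests of sequencing run and of the spread of the gel replicates were chosen after. The genes listed first are those named by the rule whose effects on both coatings were called, with opposite signs. This selection was made after values were seen, in place of the largest differences.

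The effects of C170 and C301 against uncoated silicone were both called, with opposite signs, for 154 genes. For all 154 edgeR's test of the difference passed too, and the naming rule took 8 of them. As C301 minus C170 on the log2 scale, KCNQ3 was at -1.87 ± 0.11 (1.5 on C170 and -0.37 on C301) and PRTN3 at -0.98 ± 0.11 (0.64 and -0.33). The chemokine gene CCL20 was at 1.81 ± 0.15 (-1.35 on C170 and 0.46 on C301) and the cytokine gene IL1B at 1.28 ± 0.1 (-0.43 and 0.85). The collagen genes COL6A1 and COL6A2 were at 0.61 ± 0.04 (-0.32 and 0.29) and 0.59 ± 0.05 (-0.38 and 0.21). The metabolic enzyme genes ME1 and MTHFD2 were at 0.57 ± 0.08 (-0.19 and 0.38) and 0.5 ± 0.05 (-0.15 and 0.35). The largest of the 8 adjusted p-values of edgeR's test of the difference was 1.53e-07. Because the genes were selected for called effects of opposite sign, a passing difference was to be foreseen and is no separate support.

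LXR target and cholesterol biosynthesis genes were lower on both coatings than on uncoated silicone, with medians over 40 members of -1.43 on C170 and -1.64 on C301. With trends in gene length and GC content removed, the medians were -1.38 ± 0.13 and -1.59 ± 0.06 (SD over runs), which argues against those trends as the whole cause. The difference was present in each run, the smallest median being -1.36. Each run held 1 library of each material, so a shift common to a run cancels here by design. Uncoated silicone had the highest mean of both lists among the 13 materials (cholesterol biosynthesis 1.42 and LXR 2, centred log2 CPM). The coatings were within the range of the other groups for cholesterol biosynthesis (0.17 on C170 and 0.02 on C301) and at -0.84 and -0.45 for LXR. The difference thus includes a high level on the uncoated surface. The labels name no difference in plate, lysis, seeding or differentiation between the 3 silicones. The material stays open as a biological explanation, untested.

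Type I interferon-stimulated genes spread between replicates of one material, with a mean log2 CPM from 3.36 to 4.37 on SIBS-Flat and from 2.95 to 3.96 on CHEM-Unc. Runs explained 6.6% of the variance within materials (permutation p = 0.442, 10000 permutations within materials), which leaves most of the spread to other sources. Deviations correlated with those of log2 total count with r = 0.21 (permutation p = 0.298), rho = 0.24 (permutation p = 0.226) and r = 0.23 without the 2 farthest libraries. Depth stays open: the bound set before, an r under 0.3, was met by less than the permutation SD of 0.2, and depth was moved from excluded to open after the value was seen. No biological explanation was tested, as the labels give no difference between replicates.

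Few genes differed between the gels (65) and 10195 between the gels and the other groups. With length and GC trends as an offset the counts were 102 and 10297, and gel replicates had a median SD of 0.088 against 0.094 elsewhere, a ratio of 0.94. With the run as a block 101 genes were called between the gels, so neither these trends, nor spread, nor blocking on the run closed the gap. Each run held 1 library of each material, so a shift common to a run cancels in both contrasts by design. The contrasts also differ in precision, with a median SE of 0.088 between the gels and 0.048 against the other groups. Called genes that changed at least 2-fold numbered 3 and 1026. How much of the gap comes from precision was not tested. Handling of the gels, lysed 2 times, cannot be told apart from the material because the design confounds them.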

How the results depend on the processing

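The alternatives were planned, and the tolerance for the correlation of the coatings was changed after the values were seen, from 0.05 to the SD over runs of 0.064. No named gene reversed with DESeq2, its size factors in edgeR, no low-count filter, the run as a block or a library left out. No list call reversed with those alternatives, DESeq2 excepted as it was not run for lists, or with an estimated correlation. Of 910 named-gene results, 901 kept their call with DESeq2, 8 fell short and 1 had no adjusted p. With DESeq2's size factors in edgeR 909 kept it and without a low-count filter 908. With a library left out, 19507 named-gene results kept their call and 242 did not, and 4145 list results did and 181 did not. With an estimated correlation, list calls went from 204 to 35. Size factors of DESeq2 moved median log2 fold changes by at most 0.01.

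A fold change of at least 1.5 was passed by 253 genes for the pores, 0 for SIBS, 955 for C170, 1091 for C301, 199 for C301 against C170, 4 for the meshes, 0 for the gels and 407 for the shells. For groups against the others it was passed by 383 (pores), 22 (SIBS), 958 (silicones), 23 (meshes), 1568 (gels) and 938 (shells). Fewer genes pass by construction. Between the gels, 65 genes became 247 without a low-count filter and 125 with the gels fitted alone, and between the meshes 518 became 965 with the meshes fitted alone; the cause was not tested. DESeq2 called 87 between the gels and 836 for SIBS.

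With the sequencing run as a block, paired by number, the count between the gels went from 65 to 101. Other counts stayed within 1.5 times, with 1013 for SIBS and 655 for the meshes. Blocked, 5 list calls passed the threshold no longer: fusion genes (adjusted p = 0.0568) and PPAR targets (0.0539) for C301 against uncoated silicone, mitochondrial genes for the meshes (0.0568), and inflammasome genes for meshes (0.0546) and shells (0.0558) against the other groups. List calls numbered 202 with the block and 204 without, so others were gained, and all 910 named-gene results kept their call.

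Leaving out each library in turn gave 284 to 1316 genes for SIBS, 267 to 427 for the meshes and 13 to 90 for the gels, with fewer samples in each fit. The other counts stayed within 1.5 times, and the correlation of the coatings ran from 0.708 to 0.778. At this depth the self-test recovered 46% of 1.2-fold changes in genes of at least 2 CPM, so small changes can be missed. Genes below 2 CPM were not among those changed in it.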

Other observations

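The tests of other splits of the samples were chosen after the results were seen. The gene lists described first were fixed before the data were examined.

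Some glycolysis and hypoxia genes were higher on SIBS topography, where 6 of 31 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000987, adjusted p = 0.0445 with an estimated correlation), with the hexokinase gene HK2 (0.34 ± 0.06). On 30 µm pores 10 of 31 rose and 0 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000241, adjusted p = 0.0652 with an estimated correlation), with NDRG1 (0.7 ± 0.06) and HK2 (0.65 ± 0.06). On gels 8 of 31 rose and 20 fell (8 and 20 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.0712 with an estimated correlation), with SLC2A1 (-0.66 ± 0.03). Fusion and giant cell genes were lower there, as 5 of 22 rose and 15 fell (5 and 15 adjusted over the list alone, camera adjusted p = 0.00604, adjusted p = 0.0925 with an estimated correlation), with SRC (-1.05 ± 0.06) and MMP9 (-1.06 ± 0.04). Replication-dependent histone genes, which mostly lack polyA tails, are measured only in part in polyA libraries. On gels 0 of 6 rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.00496, adjusted p = 0.185 with an estimated correlation), while cell cycle genes were higher there. On silicones 6 of 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.155 with an estimated correlation), with H2AC6 (1 ± 0.03), while cell cycle genes were lower. On the textured shell, dendritic cell markers were higher in most cases: 8 of 13 rose and 2 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.0818 with an estimated correlation), with CD1C (1.26 ± 0.11) and CD1A (1.16 ± 0.12).

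A split of 6 libraries into 3 and 3 can be made in 10 ways, too few for a share under 0.05. The real split and the highest other gave 3678 and 59 genes for the pores, 866 and 547 for SIBS, 6213 and 1 for C170, 6421 and 1 for C301, 3747 and 18 for C301 against C170, 518 and 0 for the meshes (edgeR), 65 and 140 for the gels, and 4505 and 5 for the shells. As many genes as in the real split came from 1 split, the real one, in each comparison except the gels, where it was 2. For SIBS the split with 547 genes put SIBS-Flat replicate 3 with SIBS-Topo replicates 1 and 3. For the gels it put replicate 1 of both gels together, along run 1 against run 2, and the blocked value was 101. Both of these splits part 1 pair of libraries of one run. Among splits that part all 3 pairs, as the real one does, the highest other was 0 for SIBS and the gels and 18 at most.

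For groups, other sets of as many materials were compared with the rest, materials weighted alike. Most of those sets mix materials of different groups, and the shares were not adjusted over the 6 groups. They rank sets of materials, so they cannot exclude chance among libraries. The gels gave 10245 genes and the highest of the other sets 9767, so that 1 of 78 sets, the real one, gave as many. The silicones gave 10019, with 10076 for the highest other and 2 of 100 drawn sets as large, the real one included. For the remaining groups chance is not excluded either. As many genes came from 15 of 78 sets for the pores (7665) and 55 of 78 for SIBS (5456). It was 66 of 78 for the meshes (4914) and 6 of 78 for the shells (8360). For the pores, SIBS, meshes and shells the highest other set, at 10245 genes, was the gels, itself a group of the design. Over all 13 materials, 13054 genes differed and 143 at most in the other label sets of 100, the real one included. A chance assignment of labels to libraries is thus unlikely to account for the count. Labels were permuted over single libraries, without regard to runs. Chance among cultures is not excluded, as whether replicates came from separate cultures is not stated.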
